A study of Gallus gallus with 10 samples.

How the data were processed

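Retinas were dissected from chicken embryos at embryonic day 6, electroporated with a pair of reporter plasmids and kept as explants for 9 or 15 days. They were dissociated with trypsin, and the DsRed and GFP cells of the same explants were collected by fluorescence-activated sorting. RNA was isolated on columns and amplified to cDNA, and 6 libraries were sequenced per lane, one lane per experiment. The 5 experiments paired Rho::DsRed with Green::GFP and Red::DsRed with Green::GFP at 9 days, and Red::DsRed with Rho::GFP, Green::GFP or Violet::GFP at 15 days, each with 3 biological replicates per population. Populations are called by the promoter that marked them, so that "red cones" stands for cells sorted on the red opsin reporter.

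Per the submitters' processing notes, TopHat 1.4.0, Bowtie 0.12.7, Cufflinks 1.3.0 with Cuffdiff, edgeR, R 3.0.2 and CASAVA 1.7 and 1.8 were used with the chicken assembly galGal4, with no role or order given. For each experiment the authors deposited a Cuffdiff table of 16936 loci and an edgeR table of 11167 to 11555 genes. The deposited Cuffdiff tables give an FPKM value per population over its 3 replicates together, a test statistic (a score), a p-value and a q-value per locus. The authors' deposited edgeR tables give a log2 fold change, a mean expression level (logCPM) and an unadjusted p-value per gene. How reads were counted and how libraries were scaled is not stated. The tables used here hold no values per library, so the depth of each sample is unknown, and no SD or n-based error can be put beside an FPKM value.

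From these tables the standard error of a Cuffdiff log2 fold change was computed as the fold change divided by the test statistic. The two-sided normal p of the test statistic was checked against the deposited p-value, with a largest deviation under 3e-06. The deposited q-values were checked to be Benjamini-Hochberg values over the tested loci. The authors' deposited edgeR tables hold no adjusted p, contrary to what had been assumed before the data were examined, so Benjamini-Hochberg adjusted p-values were computed over the genes of each table. The direction of the authors' deposited edgeR fold changes was read from their correlation with the Cuffdiff fold changes across the 900 to 991 loci that carry an Ensembl identifier in both tables (Pearson r from 0.956 to 0.979; genes are not independent replicates). A gene was called at an adjusted p or q under 0.05. Counts of genes and overlaps between experiments were taken from the authors' edgeR tables. Overlaps were given Fisher's exact test for a departure from independence in either direction. The implied standard error of an opsin in the authors' edgeR tables is its log2 fold change divided by the normal quantile of its p-value. All folds and FPKM values of named genes, and all list values, are those of the authors' deposited Cuffdiff tables, and opsins absent from those tables come from the authors' edgeR tables. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

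Before the data were examined, 26 gene lists, the comparisons, the thresholds and a rule for naming genes were fixed. The lists hold opsins, rod and cone phototransduction, general photoreceptor genes, photoreceptor transcription factors, thyroid hormone signalling, carotenoid and retinoid handling, lipid droplets, retinoic acid and patterning, axon guidance and adhesion, synapse, ion channels, glycolysis, oxidative phosphorylation, the circadian clock, cilium, and markers of bipolar, amacrine, horizontal, ganglion, Müller glial, proliferating, pigment epithelial, immune, endothelial and mesenchymal cells and of dissociation stress. Matching by symbol gave 745 matches over all lists, to 714 distinct loci, 13 of them through an older symbol. A prefix entry counts once per locus it matched. Entries not found, or found only on joined or repeated loci, were left out. Not found were, for example, 9 of 40 photoreceptor transcription factors, 15 of 113 adhesion genes and 12 of 33 stress genes. For each list, members called in each direction were counted over all loci and with q-values adjusted over the list alone. The median log2 fold change was set against 10000 random lists drawn from loci of like mean expression, in 10 classes. The rule named the opsins, the 10 genes per direction with the largest fold change among those that carry a gene symbol and were called with at least 5 FPKM in the higher population, up to 4 called members of each list by q-value, and the 10 shared genes with a symbol per direction with the largest smaller fold change across experiments. The rule was to use genes called in the authors' edgeR and Cuffdiff tables together. Since the tables share identifiers for few loci, calls of Cuffdiff alone were used, a departure made after the tables were seen.

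Some symbols needed care. The locus listed as OPN1LW on chromosome 19 (7050568 to 7053364) lies between DOC2B and TEX14, where the current chicken annotation places pinopsin, so it was not read as red opsin. Green opsin is listed as PRA1, and SS1R, SS5R and LEPREL1 are older symbols of SSTR1, SSTR5 and P3H2. In the red and violet comparison 21 symbols had been turned into dates by a spreadsheet. Symbols were therefore taken by locus from another experiment's table, in which some entries also read like dates and stayed unresolved. A locus can join several overlapping genes, and GNAT1 occurs only in a locus joined with SEMA3F, so it was left out of the lists.

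Calls were tested on simulated data made from each table, with 200 genes changed by 2-, 4- or 8-fold. The noise was drawn from the same standard errors that the calls used. The shares recovered therefore hold only if those errors are right, and few false calls follow by construction. Cuffdiff recovered 62.7%, 74.6%, 88.1%, 55.2% and 91.0% of 4-fold changes in the order rod and green, red and green at 9 days, red and rod, red and green at 15 days, red and violet, with 7, 5, 7, 6 and 5 false calls. For the authors' edgeR tables the shares were 92.5%, 97.0%, 98.5%, 82.1% and 94.0%. A test of the difference between ages, chosen after the tables had been seen, compared red over green at 15 and 9 days with the 2 standard errors combined; it recovered 145 of 200 simulated 8-fold differences with 6 false calls over 10788 genes. Alternatives were the authors' Cuffdiff calls in place of their deposited edgeR values, thresholds of 0.01 and 0.1, a minimum of a 2-fold change, filters on low values, a pseudocount of 1 FPKM and centring on the median.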

Results

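RNA of photoreceptor subtypes from the developing chicken retina was measured by sequencing amplified cDNA. The chicken retina holds rods and several kinds of cone, each of which makes its own visual pigment (opsin). Retinas taken at embryonic day 6 were electroporated with a DsRed and a GFP reporter, each driven by an opsin promoter, and kept in culture as explants for 9 or 15 days. The 2 fluorescent populations were then sorted by flow cytometry. There were 5 such experiments: rods against green cones and red against green cones at 9 days, and red cones against rods, against green cones and against violet cones at 15 days. Each population had 3 biological replicates, and no library served in more than 1 experiment. The deposited tables hold values pooled over the replicates, so the depth of a library and the spread between libraries could not be seen. The precision of each experiment is therefore given by the standard errors in the authors' Cuffdiff tables. The median standard error of a log2 fold change was 0.45 for rods against green cones at 9 days, 0.38 for red against green at 9 days, 0.28 for red against rod, 0.51 for red against green at 15 days and 0.29 for red against violet.

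Every pair of populations differed in gene expression, with the most calls in red cones against rods. The experiments differed in precision, so the counts do not rank the size of the differences. In the authors' edgeR tables, 2324 of 11395 genes passed an adjusted p of 0.05 between red cones and rods, 1268 of them higher in red cones and 1056 higher in rods. Red and violet cones differed in 1456 of 11555 genes, with 860 higher in red and 596 higher in violet cones. Red and green cones differed in 889 of 11167 genes at 9 days (493 higher in red, 396 in green) and in 535 of 11307 genes at 15 days (271 and 264). Rods and green cones at 9 days differed in 413 of 11395 genes, 245 of them higher in rods. The authors' Cuffdiff tables of the same libraries called fewer genes in each experiment, namely 1087, 546, 334, 212 and 126 in the order just given. At 15 days the Cuffdiff calls between red and green cones leaned towards green, with 130 of 212 higher in green cones.

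**Figure D1:**
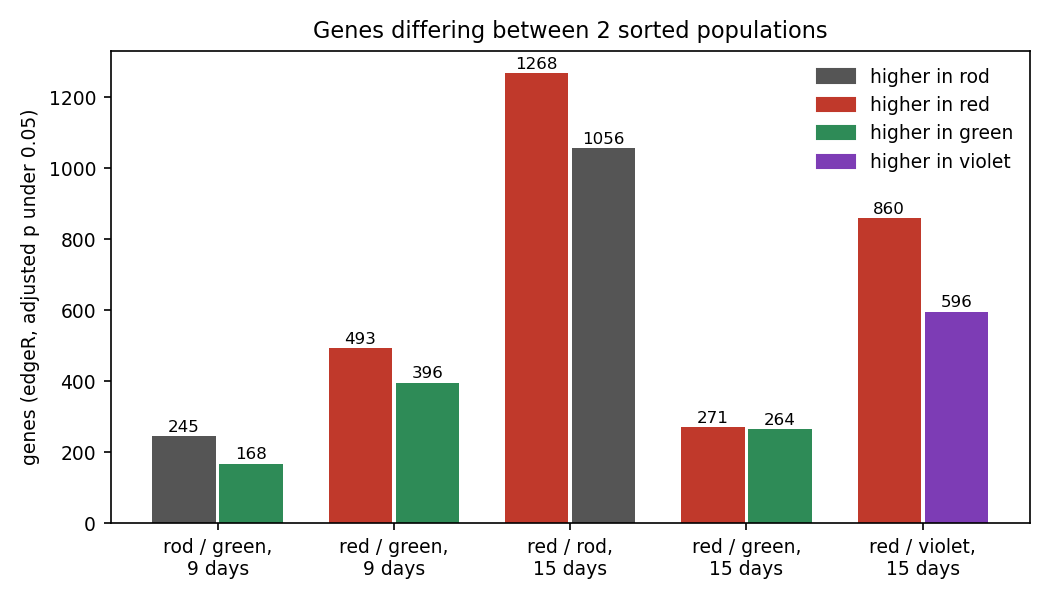
Number of genes (y axis) that edgeR called at an adjusted p under 0.05 in each of the 5 comparisons, split by the population with the higher level. The comparison of red cones with rods at 15 days has the tallest pair of bars, with 1268 and 1056 genes.

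In each comparison the opsin whose promoter had marked a population was higher there than in its partner. Rhodopsin in the authors' deposited Cuffdiff tables (RHO, galGal4 chromosome 12, 19501547 to 19505631) stood at 113 and 6.92 FPKM in rods and green cones at 9 days, a log2 difference of 4.02 ± 0.49 (SE). Between rods and red cones at 15 days it stood at 848 and 58.0 FPKM, a log2 difference of 3.87 ± 0.18. The gene for green opsin is listed as PRA1 (chromosome 26, 4496440 to 4502013). It was at 290.4 FPKM in green cones and 29.2 in rods at 9 days (log2 green over rod 3.31 ± 0.39), and at 307 and 12.6 FPKM in green and red cones at 9 days (log2 4.60 ± 0.29). At 15 days it reached 1233 FPKM in green cones against 32.5 in red cones, a log2 difference of 5.24 ± 0.47. Red, blue and violet opsin have lines of their own only in the authors' edgeR tables. There, red opsin was higher in red cones than in each partner, by 3.85 on the log2 scale over green cones at 9 days, 4.07 over green cones at 15 days, 2.37 over rods and 2.70 over violet cones (adjusted p between 1.9e-35 and 5.2e-69 at 15 days). Violet opsin was 2.64 higher in violet than in red cones (adjusted p = 3.2e-24).

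Opsins other than the one marked were also detected, and some differed between populations. Violet opsin was 3.28 higher on the log2 scale in green than in red cones at 15 days (edgeR adjusted p = 3.7e-16), while at 9 days the same difference was 0.67 and did not pass (adjusted p = 0.24). Violet opsin was also 0.93 higher in rods than in red cones at 15 days (adjusted p = 0.011). Blue opsin was 1.79 higher in red than in green cones at 9 days (adjusted p = 3.0e-07), lay on the other side at 15 days short of the threshold (log2 red over green -0.75, adjusted p = 0.63), and was 1.31 higher in violet than in red cones (adjusted p = 9.0e-07). Green opsin was higher in rods than in red cones at 15 days, by 1.19 ± 0.18 in the deposited Cuffdiff table (q = 2.5e-09). Rhodopsin was at 64.0 and 76.3 FPKM in red and green cones at 15 days, with no difference beyond its error (log2 -0.25 ± 0.38, Cuffdiff q = 1), and at 54.6 and 36.7 FPKM in red and violet cones (log2 0.57 ± 0.23, q = 0.19). Red opsin was 1.52 higher in green cones than in rods at 9 days, short of the threshold in edgeR (adjusted p = 0.065).

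**Figure D2:**
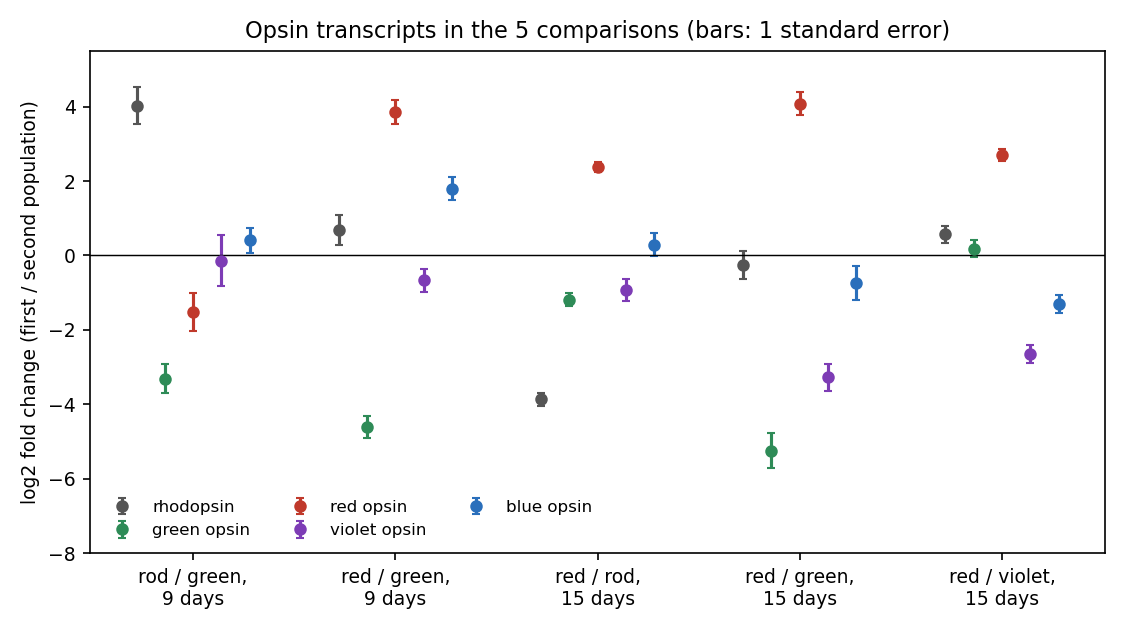
Log2 fold change (first over second population, y axis) of 5 opsin transcripts in the 5 comparisons, with bars of 1 standard error, from Cuffdiff for rhodopsin and green opsin and implied by the edgeR p-value for red, blue and violet opsin. Green opsin falls to -5.24 in red against green cones at 15 days, where violet opsin is at -3.28.

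Rods at 9 days stood apart from green cones by high transcripts of the rod visual cascade, of the transcription factor MAFA and of the monoamine-degrading enzyme MAOA. MAOA in the authors' deposited table was 30.5 times higher in rods (log2 4.93 ± 0.70; chromosome 1, 110613429 to 110658911) and MAFA 26.9 times higher (64.7 and 2.41 FPKM, log2 4.75 ± 0.67; chromosome 2, 148240819 to 148241680). Of 6 rod phototransduction genes tested, 4 were called higher in rods and 0 lower, and adjusted over the list alone 5 were called, all higher in rods. They were PDE6B, the beta subunit of rod phosphodiesterase (440.2 and 21.8 FPKM, log2 4.34 ± 0.36), SAG, the rod arrestin (log2 4.14 ± 0.54), PDE6G (4.14 ± 0.56) and the ion exchanger SLC24A1 (3.18 ± 0.58). The list had a median log2 of 3.66, above each of 10000 random lists matched on expression. The cone phototransduction list lay on the other side, with a median of -0.87, below each random list. None of its 9 tested members was called over all genes by Cuffdiff, and adjusted over the list alone 6 were called higher in green cones.

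Ion channels and an enzyme of serotonin synthesis were among the other genes higher in rods at 9 days. Of 97 channel genes tested, 4 were called higher in rods and 0 lower (5 when adjusted over the list alone): the potassium channels KCNH8 (log2 3.98 ± 0.56) and KCNV2 (2.24 ± 0.46), the anoctamin ANO4 (3.90 ± 0.65) and the pacemaker channel HCN1 (1.64 ± 0.37). TPH1, tryptophan hydroxylase, was at 75.0 and 7.23 FPKM (log2 3.38 ± 0.48). It was the 1 called member of 16 in the clock and melatonin list, where 1 was called when adjusted over the list alone. The retinal guanylate cyclase GUCY2F was 3.05 ± 0.51 higher, the nuclear receptor ESRRB 1.99 ± 0.46, the collagen-modifying enzyme LEPREL1 4.04 ± 0.52 and the metalloprotease ADAM12 3.81 ± 0.46. The glial glutamate transporter SLC1A3 was 1.84 ± 0.42 higher in rods. It was the 1 called marker of 16 for Müller glia and progenitors (2 when adjusted over the list alone), a list whose median of 0.35 lay above each random list.

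The genes higher in green cones than in rods at 9 days included the protocadherin PCDH10 and the signal transducer SMAD9. PCDH10 stood at 61.7 FPKM in green cones and 7.57 in rods (log2 green over rod 3.03 ± 0.36) and SMAD9, a transducer of bone morphogenetic protein signals, was 3.02 ± 0.54 higher. The metalloprotease ADAMTS6 (3.03 ± 0.34), IL16 (3.22 ± 0.55), LASP-2 (2.40 ± 0.43), ROPN1L (2.32 ± 0.55), ATP6AP1L (2.10 ± 0.36), RASL10B (2.09 ± 0.51) and the phosphatase DUSP5 (1.99 ± 0.37) completed the genes with the largest differences in the authors' deposited table. Of 84 axon guidance and adhesion genes, 5 were called higher in green cones and 0 in rods (5 when adjusted over the list alone), and the median of -0.02 lay inside the random range. DSCAM was at 1.43 ± 0.34 and PCDH17 at 1.67 ± 0.36, both higher in green cones. Among 29 photoreceptor transcription factors, 3 were higher in green cones, SALL1 (1.65 ± 0.44) and SMAD9 among them, and 2 in rods (5 when adjusted over the list alone). The retinol transporter STRA6 (1.63 ± 0.44) and the lipid droplet protein CIDEA (1.54 ± 0.32) were higher in green cones. Each was the single called member of its list, with 22 carotenoid and retinoid genes tested (2 called when adjusted over the list alone) and 31 lipid genes (1 likewise). This experiment had the lowest count of calls in both tables. In the simulation from its Cuffdiff standard errors, 10.4% of genes changed by 2-fold and 62.7% of those changed by 4-fold were recovered.

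**Figure D3:**
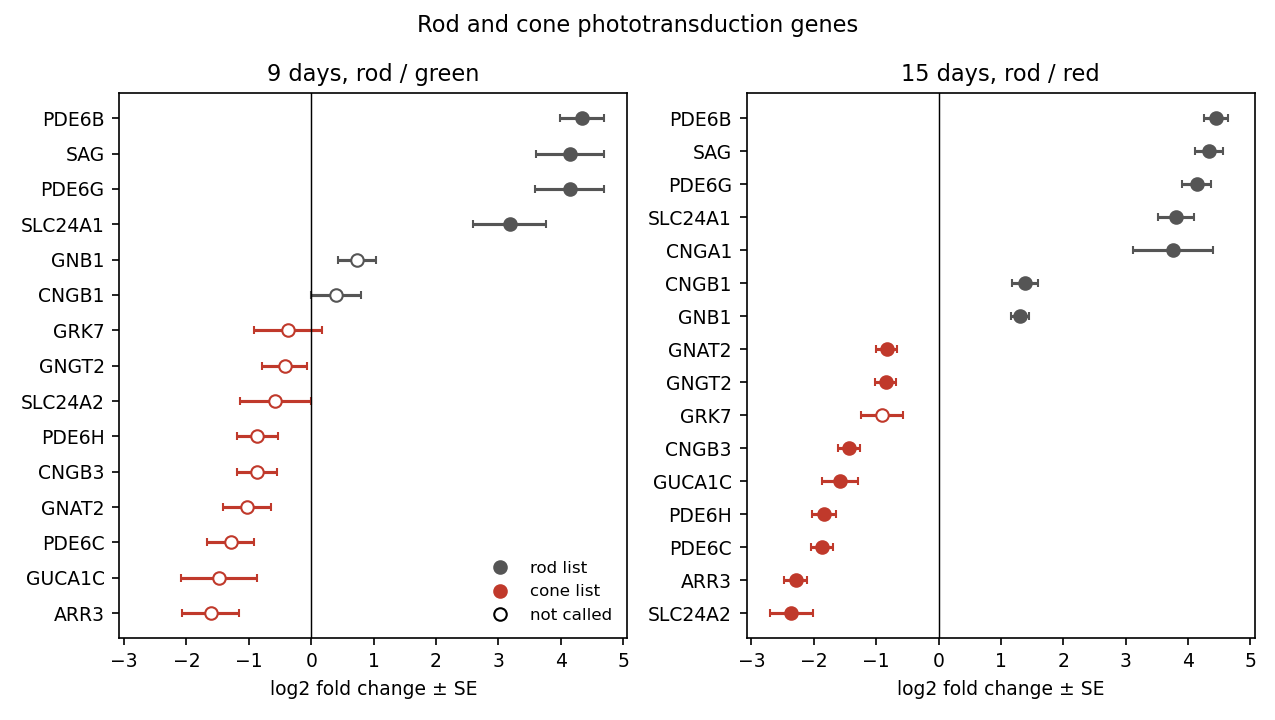
Log2 fold change with its standard error (x axis) of the tested rod (grey) and cone (red) phototransduction genes for rods over green cones at 9 days and rods over red cones at 15 days, open circles marking genes Cuffdiff did not call. The rod genes reach 4.34 at 9 days and the cone genes lie to the left of 0 in both panels.

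Genes higher in red than in green cones at 9 days included the thyroid hormone receptor THRB, the receptor KIT, the laminin LAMA1 and the channel KCNA10. In the authors' deposited table THRB (chromosome 2, 37844467 to 37965174) stood at 105 and 8.33 FPKM in red and green cones (log2 3.66 ± 0.33), and its partner RXRG, a retinoid X receptor, was 1.47 ± 0.23 higher. They were the 2 called members of 12 thyroid hormone genes, also when adjusted over the list alone. The receptor tyrosine kinase KIT was at 386 and 33.2 FPKM (log2 3.54 ± 0.25) and the laminin LAMA1 at 24.2 and 1.34 FPKM (4.17 ± 0.39). The transcription factors TAL2 (4.34 ± 1.01) and PITX3 (3.12 ± 0.43), the potassium channel KCNA10 (3.54 ± 0.52), the kinase PRKCH (3.75 ± 0.58), the actin nucleator COBL (3.11 ± 0.40) and TCERG1L (3.28 ± 0.63) were also among the genes with the largest differences. The symbol GSTA3 (3.77 ± 0.52) marks 2 loci, so its value is uncertain.

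Cone phototransduction was higher in red than in green cones at 9 days. Of 9 genes tested, 3 were called higher in red and 0 higher in green cones, and 4 were called when adjusted over the list alone. These were ARR3, the cone arrestin (2.46 ± 0.33), SLC24A2 (1.82 ± 0.50) and PDE6H (0.82 ± 0.23). The rod channel subunit CNGB1 was 1.20 ± 0.34 higher in green cones, the 1 call of 6 in the rod list (also 1 when adjusted over the list alone). Of 21 general photoreceptor genes, 2 were higher in red cones, CABP4 (1.44 ± 0.38) and GUCA1A (1.28 ± 0.14), and 3 in green cones, among them RS1 (1.43 ± 0.24) and RGS9 (0.84 ± 0.24); 9 were called when adjusted over the list alone. BCDO2, which cleaves carotenoids, was 2.25 ± 0.37 higher in red cones, the 1 call of 20 (3 when adjusted over the list alone). Glycolysis genes had 3 calls of 19, each higher in red cones and each kept when adjusted over the list alone: ENO1 (1.33 ± 0.24), SLC16A1 (1.44 ± 0.45) and PKM (0.50 ± 0.15). The oxidative phosphorylation list of 65 genes had a median of 0.30, above each random list, with 0 members called in Cuffdiff, also when adjusted over the list alone.

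Adhesion genes went both ways between red and green cones at 9 days. Of 74 tested, 8 were higher in red and 12 in green cones (14 and 16 when adjusted over the list alone). The related adhesion molecules DSCAM and DSCAML1 lay on opposite sides: DSCAM was 2.98 ± 0.24 higher in green cones and DSCAML1 2.44 ± 0.28 higher in red cones. PCDH10 was 2.67 ± 0.29 higher in green cones. Other genes with large differences in favour of green cones were LASP-2 (3.87 ± 0.50), ADAMTS6 (3.52 ± 0.32), SMAD9 (3.41 ± 0.53), the signalling ligand WNT9A (2.70 ± 0.72), the transcription factor TFCP2L1 (2.57 ± 0.38), SHISA6 (2.53 ± 0.43) and the prostaglandin-degrading enzyme HPGD (2.53 ± 0.79). Synapse genes had 4 members higher in red, PSD2 at 1.87 ± 0.30, and 2 higher in green cones out of 45 (6 when adjusted over the list alone).

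Markers of other retinal neurons had higher medians in the red than in the green population at 9 days. The median was 0.68 over 13 amacrine markers, 1.06 over 8 horizontal cell markers, 0.70 over 8 ganglion cell markers and 0.51 over 11 bipolar markers. Each lay at or above the 99.75 percentile of random lists. Calls were 2, 1, 0 and 0 in that order, all higher in red cones, and 5, 4, 3 and 1 when adjusted over the list alone. The calcium-binding protein CALB1 was 4.09 ± 0.75 higher in red cones and the gap junction protein GJD2 1.62 ± 0.33. Among proliferation markers, 1 of 17 was called, CENPE, 2.88 ± 0.50 higher in green cones (also 1 when adjusted over the list alone).

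Red cones and rods at 15 days differed across the visual cascade, with the rod genes higher in rods and the cone genes higher in red cones. All 7 tested rod phototransduction genes were called higher in rods, also when adjusted over the list alone, with a median log2 red over rod of -3.81. In the authors' deposited table PDE6B stood at 485 FPKM in rods and 22.1 in red cones (log2 rod over red 4.45 ± 0.19), SAG at 356 and 17.7 (4.33 ± 0.22), and PDE6G was 4.14 ± 0.24 higher. Of 9 cone genes, 8 were called higher in red cones and 0 higher in rods, with 9 called when adjusted over the list alone. ARR3 was at 378 and 77.1 FPKM in red cones and rods (log2 2.29 ± 0.19), PDE6C was 1.87 ± 0.18 higher and PDE6H 1.83 ± 0.19 higher in red cones. Of 21 general photoreceptor genes 7 were higher in red cones, GUCA1A at 1.54 ± 0.07, and 3 in rods, GUCY2F at 3.62 ± 0.27 and PRPH2 at 1.21 ± 0.16 (13 when adjusted over the list alone).

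Transcription factors divided red cones from rods in both directions. Of 29 tested, 8 were higher in red cones and 7 in rods (8 and 9 when adjusted over the list alone), with a median of 0.30 towards red cones, above each random list. THRB (95.1 and 11.2 FPKM, log2 3.08 ± 0.24), RXRG (2.06 ± 0.18) and SAMD7 (2.65 ± 0.22) were higher in red cones. MAFA (4.10 ± 0.43) and SAMD11 (2.38 ± 0.11) were higher in rods, so the related proteins SAMD7 and SAMD11 lay on opposite sides. THRB and RXRG were the 2 calls among 13 thyroid hormone genes (3 when adjusted over the list alone). The retinoic acid receptor RARB was 1.85 ± 0.39 higher in red cones and TBX5 1.19 ± 0.39 higher in rods, the 2 calls of 8 patterning genes (2 when adjusted over the list alone).

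The genes higher in rods than in red cones included several channels, the somatostatin receptor listed as SS1R (41.9 against 2.24 FPKM, log2 rod over red 4.23 ± 0.42) and GCH1, which makes the cofactor of tryptophan hydroxylase (4.07 ± 0.63). MAOA was 4.14 ± 0.37 higher in rods, the galactosyltransferase B3GALT5 4.32 ± 0.89 and the vesicle protein RAB3B 3.90 ± 0.47. Of 86 channels, 13 were higher in rods and 6 in red cones, also when adjusted over the list alone, and the median of 0.04 (red over rod) lay inside the random range. Called channels were KCNH8 (3.76 ± 0.33), ANO4 (3.75 ± 0.44) and KCNV2 (3.53 ± 0.30) higher in rods and ANO2 (1.49 ± 0.20) in red cones. In the clock and melatonin list TPH1 (3.47 ± 0.24) and AANAT (1.17 ± 0.26) were higher in rods and CRY2 (0.51 ± 0.17) in red cones, 3 calls of 16 (4 when adjusted over the list alone). Synapse genes had 8 calls for red cones and 4 for rods of 46, and cilium genes 2 and 5 of 37, both unchanged when adjusted over the list alone.

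Red cones at 15 days were higher than rods in LAMA1 (log2 3.29 ± 0.29), the transcription factor IRF6 (3.19 ± 0.61), KIT (3.07 ± 0.19), the transporter SLC16A12 (2.81 ± 0.64), the purinergic receptor P2RY3 (2.78 ± 0.58), PDGFRA (2.75 ± 0.36), KCNA10 (2.73 ± 0.50) and PPP1R3B, a glycogen-targeting phosphatase subunit (2.73 ± 0.35). Lipid genes had 5 calls for red cones and 1 for rods of 27 (8 when adjusted over the list alone). The apolipoprotein APOA1 (146 and 42.5 FPKM, log2 1.78 ± 0.22) and CIDEA (1.24 ± 0.19) were among them, and the carotenoid receptor SCARB1 was 1.94 ± 0.30 higher. Glycolysis genes had 4 calls of 18, each higher in red cones (6 when adjusted over the list alone, 1 of them higher in rods), LDHB at 1.26 ± 0.17. Oxidative phosphorylation had 5 of 65, also when adjusted over the list alone. Axon guidance genes were split 13 to 13 of 79 (15 and 14 when adjusted over the list alone), with CDH18 (1.87 ± 0.17) higher in red cones and NRXN1 (1.56 ± 0.18) and PLXNB2 (1.53 ± 0.17) in rods. Ganglion cell markers were higher in red cones, with 4 of 8 called (ATOH7, NEFH, NEFM and STMN2) and 5 when adjusted over the list alone. Amacrine and horizontal markers had 1 call of 13 and 1 of 8, both higher in red cones. Bipolar markers had 2 of 11, both higher in rods. These calls were unchanged when adjusted over the list alone, and the 3 medians lay inside the random range.

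Red and green cones at 15 days again differed by THRB, KIT and LAMA1 on the red side, while the green side held immune genes beside green opsin. LAMA1 in the authors' deposited table was 34.7 times higher in red cones (log2 5.12 ± 0.71), CALB1 4.91 ± 1.02 higher, THRB 4.39 ± 0.47 (96.4 and 4.60 FPKM), TAL2 4.12 ± 0.80, PITX3 4.10 ± 0.81, ANKRD5 3.65 ± 0.87, KIT 3.57 ± 0.36, KCNA10 3.51 ± 0.91, PDGFRA 3.24 ± 0.73 and COCH 2.91 ± 0.81. RXRG was 1.97 ± 0.35 higher, so THRB and RXRG were again the 2 calls among 14 thyroid hormone genes (2 when adjusted over the list alone). Of 9 cone phototransduction genes, 2 were called higher in red cones, ARR3 (1.83 ± 0.34) and SLC24A2 (2.17 ± 0.57), and 0 higher in green cones (4 when adjusted over the list alone). Of 79 adhesion genes 5 were higher in red cones, CNTN3 (2.60 ± 0.63) and LRFN5 (2.36 ± 0.57) among them, and 2 in green cones, DSCAM (1.95 ± 0.36) among them (14 when adjusted over the list alone).

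Markers of other retinal neurons and lists of synapse and channel genes lay on the red side at 15 days as well. The medians in red over green cones were 0.94 over 8 ganglion, 0.85 over 8 horizontal and 0.32 over 11 bipolar cell markers, 0.42 over 46 synapse genes and 0.34 over 82 channels, each above the random range, which for the bipolar list did not hold with a pseudocount of 1 FPKM. The median of 0.34 over 12 amacrine markers lay inside it. Calls for red cones were 1 each among ganglion (NEFM, 2.62 ± 0.72), horizontal (CALB1), synapse (PSD2, 2.87 ± 0.44) and amacrine genes (GJD2, 1.51 ± 0.35) and 2 among channels, with 1 channel called for green cones and 0 bipolar markers called. When adjusted over the list alone 4 ganglion, 1 horizontal, 0 bipolar, 2 synapse, 3 channel and 1 amacrine genes were called.

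Immune transcripts were higher in the green population at 15 days. Of 9 blood and immune markers tested, 6 were called higher in green and 0 higher in red cones, and 8 were called when adjusted over the list alone, with a median log2 red over green of -3.72 that lay below each random list. The scavenger receptor MARCO stood at 15.5 FPKM in the green and 0.173 in the red population (log2 green over red 6.49 ± 1.06). The complement genes C1QA (4.86 ± 0.77), C1QB (5.59 ± 0.90) and C3D (5.43 ± 0.83), the receptors TLR4 (5.17 ± 0.77) and IL1R2 (4.86 ± 1.21), the antibacterial protein BPI (5.41 ± 0.87), the chemokine K60 (6.26 ± 1.88) and RSFR (92.4 against 2.39 FPKM, 5.27 ± 0.69) made up, beside green opsin, the rest of the genes with the largest differences. The heme-degrading enzyme HMOX1 (3.46 ± 0.70) and the scavenger receptor CD36 (5.63 ± 1.60), from the stress and carotenoid lists, were higher in the green population too. Of the 130 Cuffdiff calls higher in green, 73, green opsin among them, were at least 4 times higher there than in each of the 9 other populations, a level set across separately normalized tables. The green populations at 9 days had 1 such call of 141 beside red cones and 0 of 43 beside rods. At 9 days 5 immune markers were tested between red and green cones, with a median of -2.40, 0 calls, and 2 higher in green cones when adjusted over the list alone. Without the 73 transcripts, 57 calls remained higher in green cones at 15 days. In the simulation from this experiment's Cuffdiff standard errors, 5.97% of genes changed by 2-fold and 55.2% of those changed by 4-fold were recovered.

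Genes higher in violet than in red cones at 15 days included the T-box factors TBX4 and TBX2, the cadherins FAT1 and FAT4 and the semaphorin SEMA3C. TBX4 in the authors' deposited table was 8.46 times higher in violet cones (log2 violet over red 3.08 ± 0.58; chromosome 19, 7588092 to 7610720) and TBX2, on the same chromosome, was at 161 against 40.2 FPKM (2.01 ± 0.21; 7630832 to 7638493). SEMA3C was 2.76 ± 0.31 higher in violet cones, the Wnt receptor FZD4 2.75 ± 0.31, FAT4 2.69 ± 0.23 (158 against 24.5 FPKM) and FAT1 2.48 ± 0.21. The fatty acid transporter SLC27A6 (2.67 ± 0.42), TMEM74 (2.43 ± 0.44), LASP-2 (2.42 ± 0.37), FGF13 (2.31 ± 0.40) and ISOC1 (2.29 ± 0.36) followed. Of 29 photoreceptor transcription factors 5 were higher in violet and 6 in red cones (10 and 7 when adjusted over the list alone), and of 76 adhesion genes 13 and 12 (17 and 17 when adjusted over the list alone). The transcription factor median of -0.22 lay on the side of violet cones, below the random range, and the adhesion median of 0.08 on the side of red cones, above it. STRA6 was 1.97 ± 0.23 and the receptor NOTCH1 1.63 ± 0.26 higher in violet cones. NOTCH1 was the 1 called marker of 15 for Müller glia and progenitors (also 1 when adjusted over the list alone).

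Red cones held the higher levels of the cone visual cascade against violet cones. Of 9 cone phototransduction genes 7 were called higher in red and 0 higher in violet cones (8 when adjusted over the list alone), led in size by ARR3 (274 and 58.6 FPKM, log2 2.22 ± 0.22), PDE6C (1.44 ± 0.21) and PDE6H (1.39 ± 0.22). THRB was at 70.3 and 11.8 FPKM (2.58 ± 0.25) and RXRG was 2.07 ± 0.21 higher in red cones, while RXRA was 0.77 ± 0.25 higher in violet cones, 3 calls of 13 thyroid hormone genes (also 3 when adjusted over the list alone). The other large differences in favour of red were CALB1 (2.75 ± 0.42), TAL2 (2.73 ± 0.40), ANKRD5 (2.52 ± 0.44), HS3ST1 (2.46 ± 0.41), the GABA receptor subunit GABRG3 (2.36 ± 0.31), ADCY7 (5.93 and 1.05 FPKM), STAB2 (2.20 ± 0.29) and AIF1L (2.16 ± 0.26). SAMD11, which was higher in rods than in red cones, was 1.23 ± 0.14 higher in red than in violet cones. Lipid genes had 5 calls for red and 1 for violet cones of 28 (9 when adjusted over the list alone), and synapse genes 7 and 2 of 43 (11 when adjusted over the list alone). Horizontal, amacrine and ganglion cell markers had medians of 0.79, 0.55 and 0.86 in favour of red cones, with 1, 2 and 1 called of 7, 12 and 7 (1, 2 and 5 when adjusted over the list alone, 1 of the ganglion cell markers then higher in violet cones). Bipolar markers lay on the other side, with a median of -0.18 inside the random range. Of these, 2 of 11 were called, both higher in violet cones (also 2 when adjusted over the list alone).

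The red and green difference was shared between the ages. Red cones carried DsRed and green cones GFP at both, so reporter and cone type cannot be told apart. Among 10866 genes tested at both ages in edgeR, 176 were higher in red cones at both, where independent lists would share 11.3 (Fisher's exact test, p = 4.2e-188). For green cones 131 were shared against 8.26 (exact p = 2.6e-134), and 0 genes were called in opposite directions in edgeR against 1 in Cuffdiff. Across these genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.612 and a Spearman correlation of 0.462. In the authors' deposited Cuffdiff tables THRB was 3.66 ± 0.33 and 4.39 ± 0.47 higher in red cones at 9 and 15 days, the melanopsin gene OPN4-1 2.84 ± 0.36 and 2.90 ± 0.40, and LRIT3 2.60 ± 0.48 and 2.85 ± 0.49. On the green side LASP-2 was 3.87 ± 0.50 and 4.02 ± 0.55 higher, ADAMTS6 3.52 ± 0.32 and 3.18 ± 0.43, SMAD9 3.41 ± 0.53 and 3.24 ± 0.60, FZD4 2.19 ± 0.59 and 2.93 ± 0.57, FAT4 2.27 ± 0.25 and 2.65 ± 0.35, and the matrix protein SPARC 2.12 ± 0.15 and 1.91 ± 0.17. The overlap had fewer shared genes with Cuffdiff, 61 for red and 28 for green cones.

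**Figure D4:**
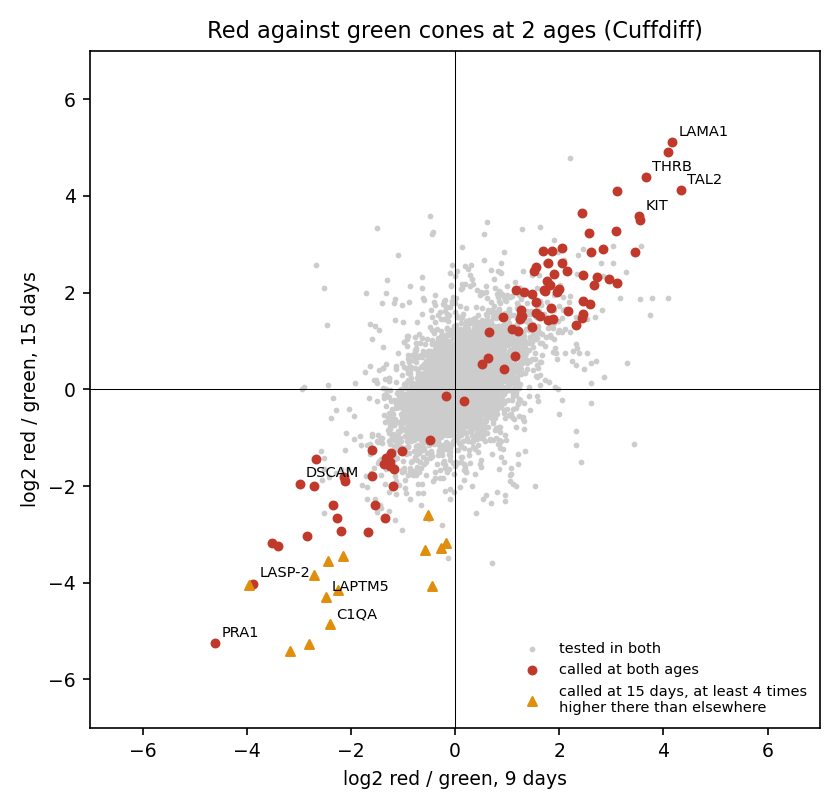
Cuffdiff log2 fold change of red over green cones at 9 days (x axis) against 15 days (y axis), each point a gene tested at both ages, red where called at both and orange where called at 15 days and at least 4 times higher in the 15-day green population than in each other population. The genes called at both ages follow the diagonal, as LAMA1 does with 4.17 and 5.12, except TCF12 at 0.18 and -0.25. The orange genes lie below -2.

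Rods differed from cones by a shared set of genes at both ages, though the age, the cone partner and the reporter colours differed between the 2 experiments. Among 11045 genes tested in both in edgeR, 172 were higher in rods in both, against 21.9 for independent lists (Fisher's exact test, p = 2.7e-127). For cones 59 were shared against 17.5 (exact p = 3.5e-18), and 29 genes were called in opposite directions. The correlation across genes, which are not independent replicates, was 0.451 (Pearson) and 0.306 (Spearman). MAOA, MAFA, PDE6B, SAG, PDE6G, RHO, KCNH8, ANO4, the sulfated-glycan epimerase gene DSEL and the adaptor GRAP2 were the 10 genes with a symbol and the largest shared difference in favour of rods. Per the authors' deposited tables, DSEL was 3.38 ± 0.41 higher in rods at 9 days and 3.60 ± 0.26 at 15 days. On the cone side the transcription factors SALL1 (1.65 ± 0.44 over rods at 9 days, 1.65 ± 0.20 at 15 days) and SALL3 (1.01 ± 0.28 and 1.11 ± 0.15) were shared, as were GUCA1A (1.46 ± 0.17 and 1.54 ± 0.07), DUSP5 (1.99 ± 0.37 and 1.56 ± 0.17), ROPN1L (2.32 ± 0.55 and 1.91 ± 0.42), the chloride channel CFTR (0.86 ± 0.14 and 2.08 ± 0.12), CIDEA (1.54 ± 0.32 and 1.24 ± 0.19), PCDH17, PALLD and EML4.

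Red cones carried a common set of genes against rods, green cones and violet cones at 15 days. In all 3 experiments red cones carried DsRed and their partner GFP, so reporter and sort channel cannot be told apart from cone type. In edgeR, 174 genes were higher in red cones in all 3 comparisons and 74 lower, of 10981 tested in all, where independent lists would share 2.33 and 1.07. With Cuffdiff, 50 were higher and 16 lower. Among loci with a gene symbol, the shared genes with the largest differences in favour of red cones were CALB1, THRB, TAL2, ANKRD5, RXRG, the adhesion protein LRFN5, ARR3, PSD2, GABRG3 and SNCAIP. Per the authors' deposited tables LRFN5 was 1.84 ± 0.28 higher than in rods, 2.36 ± 0.57 than in green and 1.84 ± 0.31 than in violet cones. The 10 with a symbol and the largest differences lower in red cones were LASP-2, ISOC1, the transcription factor NFIB, the cyclophilin PPIC, DCX, SPARC, MYO16, DSCAM, ADAMTS6 and FAT1. SPARC was 2.25 ± 0.14 higher in rods, 1.91 ± 0.17 in green and 1.35 ± 0.15 in violet cones, and the microtubule protein doublecortin, DCX, 1.37 ± 0.33, 2.27 ± 0.46 and 2.22 ± 0.25.

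**Figure D5:**
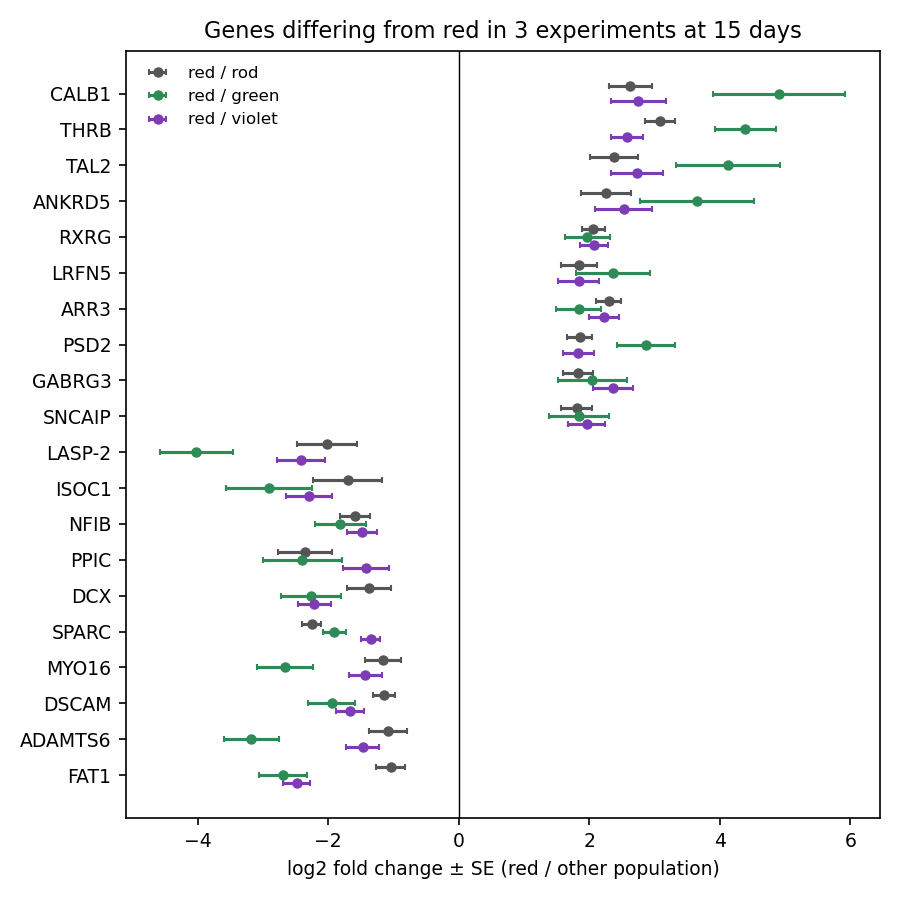
Log2 fold change with its standard error (x axis) of red cones over rods (grey), green cones (green) and violet cones (violet) at 15 days for the 20 genes named by the rule among those called in all 3 comparisons. THRB lies between 2.58 and 4.39 and LASP-2 between -4.02 and -2.01.

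Some lists were called in part in the remaining experiments. In rods against green cones at 9 days the single calls included the monocarboxylate transporter SLC16A1 (2.01 ± 0.49 higher in rods) of 18 glycolysis genes, NYX (1.99 ± 0.42, higher in rods) of 10 bipolar markers and PCDH15 (0.40 ± 0.08, higher in green cones) of 36 cilium genes, each also called when adjusted over the list alone. General photoreceptor genes had 1 call for rods and 2 for green cones of 21 (5 when adjusted over the list alone). The pigment epithelium markers had 1 call each in red against green cones at 9 and 15 days and in red cones against rods, the melanin enzyme DCT, 1.32 ± 0.24 and 1.42 ± 0.34 higher in green cones and 1.25 ± 0.17 higher in rods (1, 1 and 2 when adjusted over the list alone). The endothelial and mesenchymal list had PDGFRA in each red comparison and DCN in rods (4.85 ± 1.23), with 2, 2, 1 and 1 calls when adjusted over the list alone from red against green at 9 days to red against violet. Dissociation stress genes had 1 call in each red comparison: EGR1 (1.39 ± 0.25, red at 9 days), the locus of DUSP1 (1.12 ± 0.36, rod), HMOX1 and BTG2 (1.06 ± 0.21, violet), also when adjusted over the list alone. Between rods and green cones they had 0 calls of 18, also when adjusted over the list alone, and a median of 0.18 towards rods, above the random range. MCM6, a replication factor among the proliferation markers, was 0.37 ± 0.08 higher in rods and 0.24 ± 0.08 in violet cones than in red cones, 1 call in each list, also when adjusted over the list alone. The small differences of MCM6 and PCDH15 passed through standard errors far below the medians of their experiments. These medians were 0.28 and 0.29 for MCM6 and 0.45 for PCDH15. Further medians lay outside the random range (log2 of the first named over the second population, calls counted in either direction). Between red and green cones at 9 days these included 0.44 for Müller glia and progenitor markers (0 calls of 16, 1 when adjusted over the list alone), 0.30 for lipid genes (1 of 27, 5 likewise), 0.41 for carotenoid and retinoid genes (1 of 20, 3 likewise), 0.20 for synapse genes (6 of 45, 6 likewise), -0.13 for photoreceptor transcription factors (5 of 30, 8 likewise) and 0.14 for channels (4 of 75, 6 likewise). Between red and green cones at 15 days they included 0.28 for clock genes (0 of 15, 0 likewise), 0.21 for adhesion genes (7 of 79, 14 likewise), -0.15 for photoreceptor transcription factors (5 of 29, 6 likewise) and, for lipid genes, 0.26 towards red cones, although the 2 calls of 26, SOAT1 and FABP5, named after their values were seen, were for green cones (3 likewise). Between red cones and rods they included 0.21 for lipid genes (6 of 27, 8 likewise), 0.24 for glycolysis (4 of 18, 6 likewise) and 0.18 for oxidative phosphorylation (5 of 65, 5 likewise). Between red and violet cones they included 0.17 for oxidative phosphorylation (1 of 65, 1 likewise), 0.24 for carotenoid and retinoid genes (4 of 20, 4 likewise), 0.30 for lipid genes (6 of 28, 9 likewise), 0.31 for synapse genes (9 of 43, 11 likewise) and 0.11 for channels (7 of 79, 7 likewise).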

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

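The tests of a difference between ages and all tests of explanations given here were chosen after the results they measure had been seen.

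The red and green difference was compared between 9 and 15 days. Of 10788 genes tested by Cuffdiff at both ages, 4 differed between the ages at an adjusted p under 0.05. The log2 difference of red over green, 15 minus 9 days, was -0.62 for BCL2L1, -0.42 for TCF12, -2.19 for FAT1 and -1.79 for ENSGALG00000028602. The log2 red over green of BCL2L1 was 0.05 at 9 days and -0.57 at 15 days. TCF12 was called in opposite directions, higher in red cones at 9 days (0.18) and in green cones at 15 days (-0.25). The standard errors of BCL2L1 and TCF12 at 15 days, 0.05 and 0.06, were far below the median of 0.51 for all genes, so that their small differences passed. The spread of all z values was 0.68, below that of a calibrated test. With edgeR, 36 of 10592 genes differed, among them blue opsin (-2.54) and violet opsin (-2.60), from implied standard errors.

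Immune transcripts were higher in the green population at 15 days, where the most abundant marker, LAPTM5, stood at 78.1 against 3.95 FPKM in red cones. Of the 8 tested markers the share more than 2-fold higher in green was 1, as immune cells in the green sort would give, though some of these genes led to the test. A carry-over of immune cells with the GFP channel in every experiment at 15 days is argued against by the experiment with GFP rods, where the median log2 red over rod was 1.13 over the 4 tested markers, low in both populations and none called, and 0.30 over all 9 (LAPTM5 1.65 and 0.868 FPKM in red cones and rods), while the median red over violet was -0.37 over 4 markers, 2 of them more than 2-fold higher in violet cones and none called. Whether one of the 3 green libraries carried the signal cannot be told apart, since there is no value per library (median standard error of the markers 0.69). Immune cells in that sort may be the source, and a change in the green cones with age stays open and untested.

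Violet opsin was higher in the green than in the red population at 15 days. Whether violet cones in the green sort at 15 days were the whole source could not be decided, levels being set across separately normalized tables. The edgeR values implied 50.7 CPM of violet opsin in that sort and 54.2 in the violet population. If the violet population held violet cones alone, these would make up most of the green sort. Green opsin, however, stood at 1233 FPKM there against 43.0 in the violet population, which argues against such a share. The violet population also held an implied 94.9 CPM of red opsin, so its own share of violet cones is unknown. Were that share low, fewer violet cones in the green sort could give the 50.7 CPM. Violet cones as at least a part of the source were tested over 119 genes at least 2-fold higher in violet than in red cones. Their median log2 was -0.69 and -1.20 for red over green at 9 and 15 days and -1.38 for red over violet. The median change from 9 to 15 days was -0.36, below each random list (95% of these between -0.02 and 0.14). Low levels of the same genes in red cones alone are argued against, since red over green lay below red over rod by a median of -0.79 (interval -0.89 to -0.55) over 113 genes. Reads shared with green opsin, as the whole source, are narrowly argued against: at 9 days violet opsin was 0.14 (standard error 0.68) higher in green cones than in rods and 0.67 (0.32) higher than in red cones, where 1.46 and 1.699 would be needed from the ratio at 15 days, and the weighted shortfall over both was 1.10 or 2.04 of its standard errors, though 1.60 and 1.803 for each alone, levels being set across separately normalized tables. A change of green cones themselves with age, FAT1 included, was not tested.

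Rod genes were detected in the cone populations. If rod cells or their RNA were the whole source, all rod genes would stand at one share of their rod level. At 15 days the 8 tested genes, all called, stood at 4.56% to 40.5% of the rod level in red cones (Cochran's Q, chi-square p = 4.5e-67, resting on Cuffdiff's standard errors). At 9 days the 7 tested genes stood at 4.95% to 75.8% in green cones (chi-square p = 5.4e-23). The spread rests on GNB1 and CNGB1, at 40.5% and 38.3% in red cones at 15 days. It argues against rods as the whole source of GNB1 and CNGB1 in both sorts. GNB1 stood at 38.3% to 53.4% of the 15-day rod level in every cone population, across separately normalized tables. Of the 4 versions of Q that were run, the 2 without GNB1 and CNGB1 decide nothing, since the size of their folds left these genes out: the chi-square p was 0.19 over 6 genes at 15 days and 0.57 over the 5 genes called at 9 days. Rods or rod RNA as the source of the remaining genes, and a low level of expression in cones, stay open.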

How the results depend on the processing

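Alternatives were fixed before the data were examined, except the restriction to genes above the median of mean expression applied to the overlaps, the Cuffdiff overlaps with at least 1 FPKM, and the removal of transcripts mostly of the 15-day green population, which were chosen after the data had been seen.

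With Cuffdiff in place of edgeR, 126 genes differed between rods and green cones in place of 413, 334 in place of 889 between red and green cones at 9 days, 1087 in place of 2324 between red cones and rods, 212 in place of 535 between red and green cones at 15 days, and 546 in place of 1456 between red and violet cones; the cause was not tested. At 15 days Cuffdiff called 82 genes for red and 130 for green cones, where edgeR called 271 and 264. With edgeR genes above the median of mean expression, tested over fewer genes, 256, 574, 1494, 327 and 947 genes differed in the same order, and the split at 9 days between red and green cones turned to 280 and 294 from 493 and 396. Asking for at least a 2-fold change left 488 genes between red and green cones at 9 days, 811 between red cones and rods and 525 between red and violet cones, fewer by construction.

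The overlaps moved in the same way. Genes shared by the red and green differences at both ages were 307 with edgeR, 89 with Cuffdiff, 173 above the median of mean expression, 89 with Cuffdiff and at least 1 FPKM, and 88 with Cuffdiff without the transcripts mostly of the 15-day green population. For rods and cones the 231 shared genes became 77, 153 at an adjusted p under 0.01, 139 above the median and 77 with Cuffdiff and at least 1 FPKM. For red cones at 15 days the 248 shared genes became 66, 140 above the median and 66 with Cuffdiff and at least 1 FPKM. The cause of the change with Cuffdiff was not tested, while a stricter threshold or fewer genes lower a count by construction. Without the 73 transcripts mostly of the 15-day green population, the 130 Cuffdiff calls higher in green became 57, by construction.

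Of 50 counts under an alternative, 25 stayed within 1.5 times their main value, among them each count with a looser threshold of 0.1. The 5 counts after centring are among the 25 by construction, since centring leaves the p-values as they are, and their splits by direction were unchanged. Of 260 medians of lists under a pseudocount or a filter at 1 FPKM, 256 stayed on the same side of the random range, 2 left it, 2 entered it and 0 changed direction. Of 335 values of named genes, 294 kept their side of the threshold at 0.01 and 41 were no longer called, SALL1, STRA6 and SALL3 between rods and green cones and K60, COCH and CD36 between red and green cones at 15 days among them. With the filter at 1 FPKM, and q-values computed again over the genes left, all 335 kept their side, and the pseudocount can change neither the sign nor the q-value of a gene. Across the loci with an identifier in both tables, 158 calls were shared by edgeR and Cuffdiff, 273 were of edgeR alone, 5 of Cuffdiff alone and 0 opposite. At 0.01 these were 119, 169, 3 and 0.

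No paired analysis was possible because the tables used here hold no values per library. For the same reason another normalization, no filter on low counts, leaving out each replicate, a replicate block and other splits of the samples could not be run. Calls by both analyses together, edgeR values for the lists, and an FPKM filter on the edgeR overlaps were not run, since few loci carry an identifier in both tables. Adjusted p-values recomputed from the deposited p-values are the main values themselves. The depth of the libraries is unknown, and its effect shows only in the standard errors, whose median of 0.51 was highest between red and green cones at 15 days.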

Other observations

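The genes named next were chosen after their values were seen, and their values carry no test beyond those of the authors' deposited Cuffdiff tables. Rods held transcripts for enzymes that make and break down monoamines. At 15 days MAOA and MAOB were 4.14 ± 0.37 and 3.04 ± 0.28 higher (log2) in rods than in red cones, TPH1 3.47 ± 0.24, GCH1 4.07 ± 0.63, DDC 1.03 ± 0.20 and AANAT 1.17 ± 0.26. At 9 days MAOA, TPH1 and DDC were 4.93 ± 0.70, 3.38 ± 0.48 and 3.36 ± 0.51 higher in rods than in green cones, while MAOB (q = 0.075), GCH1 (q = 0.073) and AANAT (q = 0.58) did not pass. DDC was also higher in red than in green cones (2.01 ± 0.50) and than in violet cones (1.93 ± 0.33) at 15 days. The somatostatin receptor genes listed as SS1R and SS5R were 4.23 ± 0.42 and 4.65 ± 1.06 higher in rods than in red cones. At 9 days SS1R was 3.32 ± 0.80 higher in rods than in green cones, and SS5R (2.10 ± 0.82, q = 0.46) did not pass.

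Neighbouring genes were often called together between red cones and rods, a pattern that was noticed in the data and then tested on the same data. The bounds of the 3 tests were written before their results were seen. Of 10245 pairs of adjacent loci, 150 were called in the same direction by Cuffdiff, where permuting the calls along the genome gave a mean of 45.4 and at most 77 (permutation p = 0.0001, the smallest the permutations can give). Reads running across the end of a locus are argued against as the whole source, since among 5286 pairs at least 10000 bases apart 92 were called in the same direction against a mean of 23.3 and at most 48. Permuting within chromosome and class of mean FPKM gave a mean of 28.0 and at most 52, so that a gathering of calls on some chromosomes or at some levels did not account for the 92. KIT and PDGFRA, 72904 bases apart, were 3.07 and 2.75 higher in red cones, THRB and RARB 3.08 and 1.85. VLDLR and KCNV2 lay at -1.75 and -3.53 and TBX3 and TBX5 at -0.94 and -1.19, higher in rods. Control of neighbouring genes together may be a source. Tandem copies or related genes, such as GABRA5 and GABRB3, and genes split between loci were not excluded. Of the pairs named above, KIT and PDGFRA, THRB and RARB, and TBX3 and TBX5 are related genes as well.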
